A study of Mus musculus with 6 samples.

How the data were processed

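The samples were RNA from the distal colon of wild-type C57BL/6 male mice aged 7 weeks, collected on day 7 and sequenced as 6 libraries: 2 from mice given water, 2 from mice given 2% DSS, and 2 from mice given 2% DSS plus montmorillonite powder. Groups and replicate numbers were taken from the sample titles. The labels gave no batch, no sequencing date and no statement that libraries of a group came from separate mice. The concentration of montmorillonite was not given in the sources used here.

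The deposited table held 1 signal value per gene and library, for 20533 genes with versioned Ensembl identifiers. Per the labels, reads were mapped to mouse genome build mm10 (GRCm38); the aligner, the counting tool and the normalization tool were not given in the sources used here. In each library 100% of values were whole multiples of the smallest value above 0, to within 0.01 read, so that the deposited signal was a read count divided by 1 factor per library. The factors equalled the median-of-ratios size factors of DESeq2 computed from the recovered reads. No gene had fewer than 10 reads over the 6 libraries, so genes under that sum are not among the deposited values. All 6 columns of values were used. Gene symbols, positions and biotypes came from GENCODE M21, in which 20500 of the identifiers were found without their version, 18022 with it, and 33 not at all; 15972 genes were protein-coding.

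The recovered reads summed to 8936826 and 3741494 in water, 21481594 and 15212981 in DSS, and 6395768 and 4494666 in DSS plus montmorillonite. Between 18147 and 20398 genes had a read, mitochondrially encoded genes took 2.57% to 4.78% of reads, protein-coding genes 93.7% to 97.4%, and the 10 most abundant genes 7.02% to 9.18%. A single read was a value of 0.960 and 2.27 in water, 0.335 and 0.479 in DSS, and 1.44 and 1.82 in DSS plus montmorillonite.

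The comparisons, tests, gene lists, named genes and alternatives were set before the data were examined. The first choice was a count test, edgeR on all 6 libraries, with limma as the choice for normalised values. Since the deposited values were normalised, the main test was limma 3.58.1 with an intensity trend (R 4.3.3) on log2(value + 1), over 20307 genes with a mean value of at least 1 (226 removed), with the 3 groups in 1 fit, 3 residual and 3.52 prior degrees of freedom, two-sided, and a Benjamini-Hochberg adjusted p below 0.05. The count tests, edgeR 4.0.16 and DESeq2 1.42.0, were run on the recovered reads as alternatives. A fit of only the 4 libraries compared, with 2 residual degrees of freedom, was among the alternatives set in advance. Its use for naming genes in DSS against water, and for the median share of the DSS change, was decided after the fit of 6 libraries had called no gene.

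Gene lists were 36 sets written from textbook knowledge, 16 on programs, 17 on cell types or tissues and 3 on RNA quality, with 548 genes of which 536 were tested. Each was tested with limma camera on log2(value + 1) at a preset inter-gene correlation of 0.01, adjusted over the 36 lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. With an estimated correlation none of the 24, 17 and 23 lists changed in the 3 comparisons passed (smallest adjusted p = 0.441, 0.366 and 0.408), and fry called 0 in each. Fry's mixed test called 0, 4 and 4 lists, and in fits of 4 libraries fry called 16, 1 and 0. List medians were also computed with members without a read in a group set at the bound from a floor of 3 reads over the group, and ratios of pooled reads carry exact 95% intervals.

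The rule for named genes took, per comparison, the 6 genes with the largest positive and the 6 with the largest negative log2 fold change among genes that passed, with a mean value of at least 5 and no overlap between groups; the 2 members of each list with the smallest p among those that passed; and 14 genes fixed in advance (Lcn2, S100a8, S100a9, Il1b, Il6, Tnf, Reg3b, Reg3g, Muc2, Car1, Aqp8, Slc26a3, Tjp1, Ocln). In DSS plus montmorillonite against DSS the member with the smallest p of each program list was also taken, as values only. Some genes that the rule takes are not reported here. Other genes named, such as list members that moved against their list, were chosen after their values were seen. Folds of named genes are those of the fit on log2(value + 1).

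Principal components used genes with a mean value above 20. The share of the DSS change and the correlation of fold changes were set beside 20 simulations from negative binomial counts. The dispersions were those of the DSS and water libraries for the share and those of all 6 libraries for the correlation. The controls could not be split between the comparisons, since each part would hold 1 library. The tests were also tested on simulated data with the DSS and water dispersion and 100 genes changed 4-fold: limma recovered 74% of them in the fit of 6 libraries and 68% in that of 4, and 2% and 5% of genes changed 2-fold. Of its calls, 6 of 82 and 11 of 84 were false. With the dispersion of all 6 libraries it recovered 17% and 4% of the 4-fold changes, and 3 of 21 and 3 of 7 calls were false.

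Alternatives set in advance were DESeq2, limma voom, library size only, no filter, a filter of 20 reads in 2 libraries, only the 4 libraries compared, the replicate block, log2(value + 0.1), stricter thresholds, and each library left out in turn. Added after the data were seen were edgeR on the recovered reads in both fits, TMM factors, thinned reads, library size only or TMM factors on 4 libraries, and each DSS or water library left out of the fit of 4. Preparation used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures matplotlib 3.10.9.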

Results

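RNA was sequenced from the distal colon of wild-type C57BL/6 male mice aged 7 weeks after 7 days on water, on 2% dextran sulphate sodium (DSS, a sulphated polysaccharide that injures the colonic epithelium and is used to provoke colitis), or on 2% DSS together with montmorillonite powder, a clay mineral used as an adsorbent against diarrhoea. Each of the 3 groups held 2 libraries, 6 in all. The deposited values were normalised read counts of 20533 genes, read counts divided by 1 size factor per library. The whole reads recovered from them summed to 8936826 and 3741494 in the water libraries, 21481594 and 15212981 in the DSS libraries, and 6395768 and 4494666 in the DSS plus montmorillonite libraries. The deepest library thus held 5.74 times the reads of the shallowest. A single read corresponded to a value of 0.335 in the deepest library and 2.27 in the shallowest, so that low values were coarser in the water libraries than in the DSS libraries. The labels did not say whether the 2 libraries of a group came from separate mice, and all p-values measure the spread between these libraries.

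The 2 DSS plus montmorillonite libraries lay far apart. Replicate 1 had a correlation of log2 values across genes of 0.959 and 0.947 with the water libraries and of 0.920 and 0.885 with the DSS libraries, while replicate 2 had 0.948 and 0.954 with the DSS libraries and 0.895 with each water library. The correlation between replicates was 0.964 in water, 0.951 in DSS and 0.902 in DSS plus montmorillonite, and the median standard deviation of a gene's log2 value within a group was 0.15, 0.24 and 0.35. Neutrophil genes placed replicate 2 among the DSS libraries, whereas colonocyte genes placed it nearer water. The median of the neutrophil genes lay 0.72 above water (log2) in replicate 1 and 5.95 above it in replicate 2, against 4.96 and 6.90 in the DSS libraries. The median of the mature colonocyte genes lay at 0.30 in replicate 1 and -0.49 in replicate 2, against -1.57 and -1.66 in the DSS libraries. Genes are not independent replicates, so these correlations carry no p-value.

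**Figure D1:**
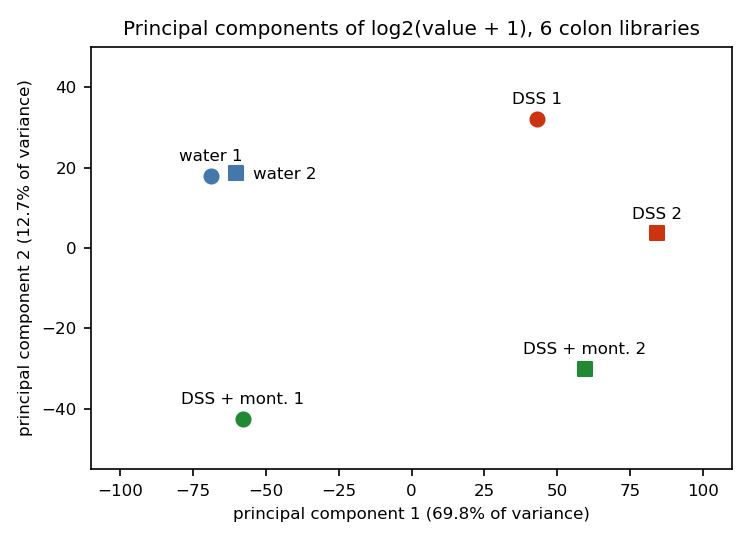
Positions of the 6 libraries on the first principal components of log2(value + 1) over 13498 genes; each point is 1 library, with circles for replicate 1 and squares for replicate 2. On component 1 (69.8% of the variance) replicate 1 of DSS plus montmorillonite sits at -58.0 beside the water libraries (-68.9 and -60.2) and replicate 2 at 59.5 between the DSS libraries (43.1 and 84.3), while on component 2 (12.7%) both lie at -42.4 and -30.0, away from the other 4 libraries (3.64 to 32.1).

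The comparison of DSS with water asks what DSS did to the colon transcriptome. Neutrophil, cytokine, protease and stromal genes were far higher in both DSS libraries than in either water library. In the limma fit of these 4 libraries, to which all counts of single genes in this comparison refer unless another is named, 17 of 26 cytokine and chemokine genes rose, 1 fell and 8 did not pass. They included Il1b, the interleukin-1 beta gene, with a normalised read count of 35.8 ± 7.23 (SD, n = 2) in water and 1165 ± 0.0802 in DSS (32.0-fold, adjusted p = 0.00148), and Il11, at 2.58 ± 0.428 and 1047 ± 560 (adjusted p = 0.00230). The member that fell, Cxcl9, encodes an interferon-induced chemokine. Among the neutrophil genes 10 of 15 rose, 1 fell and 4 did not pass. S100a9 (ENSMUSG00000056071.12, GRCm38 chromosome 3, 90692632 to 90695721), a subunit of the granulocyte protein calprotectin, had 2 reads over both water libraries and a mean of 2005 ± 977 in DSS, a ratio of 1395 with a 95% counting interval of 386 to 11520. Retnlg had no read in water and a mean of 762 ± 716 in DSS. A pair of neutrophil list members did not do what the list's name says: Cd177, a granulocyte surface protein, fell, and Ly6g, the granulocyte antigen, had values of 2137 to 3193 in all 4 libraries. In the matrix remodelling list 17 of 21 genes rose and none fell, among them the matrix metalloprotease genes Mmp10 (438-fold, log2 8.78 ± 0.48 SE), Mmp3 (331-fold, 8.37 ± 0.40 SE) and Mmp13 (51.8-fold, 5.70 ± 0.23 SE). No single gene passed in a fit of these 4 libraries without either DSS library. Counting intervals and floors cover counting error only.

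Other immune and stromal lists were higher in DSS as well. Of the complement and coagulation genes 14 of 18 rose, of the monocyte and macrophage genes 11 of 18, and of the B and plasma cell genes 12 of 14. Igha, the constant region of immunoglobulin A, had 24738 ± 1487 in water and 121363 ± 1912 in DSS (4.91-fold, limma adjusted p = 0.00691). Of the endothelial genes 9 of 11 rose, of the fibroblast genes 8 of 12, of the enteric neuron and glia genes 8 of 14, and of the red blood cell genes 3 of 5. Grem1, a bone morphogenetic protein antagonist made by fibroblasts, was 14.7-fold higher (adjusted p = 0.00256), and Vip, an enteric neuropeptide, 8.10-fold (adjusted p = 0.00643). In the list of the regenerating epithelium 5 of 16 genes rose and 1 fell, with Ereg, an EGF receptor ligand, 60.0-fold higher (adjusted p = 0.00137) and Clu 9.33-fold (adjusted p = 0.00362). In the endoplasmic reticulum stress list Xbp1 (1.77-fold) and Creld2 (1.88-fold) rose and 13 genes did not pass. All of these lists, with the cytokine, neutrophil and matrix lists, were among 12 lists that rose by limma camera, with adjusted p values from 2.77e-09 (matrix remodelling) to 0.00851 (regenerating epithelium). With an estimated correlation none passed: the adjusted p was 0.476 for neutrophils and for monocytes and macrophages and 0.441 for the other 10. The median log2 fold change was 5.42 for neutrophils (5.44 with members without a read at their bound), 3.46 for cytokines (3.17 at the bound), 2.75 for matrix remodelling (2.25 at the bound), 2.65 for B and plasma cells and 0.50 for endoplasmic reticulum stress. Adjusted over the list alone, 21 cytokine genes were higher and 3 lower, 13 neutrophil genes higher and 2 lower, 9 fibroblast genes higher and 1 lower, and 5 regenerating epithelium genes higher and 2 lower. Adjusted the same way, 20 matrix, 14 complement, 13 macrophage, 13 B and plasma cell, 11 endothelial, 10 neuronal, 4 red blood cell and 2 stress genes were higher and none lower. The same numbers in the fit of 6 libraries were 16 and 2, 12 and 1, 8 and 0, and 5 and 1, and for the other 8 lists 19, 10, 3, 13, 9, 9, 3 and 0 higher. The regenerating epithelium list did not pass without DSS replicate 2, and no single gene passed in the fit of the 4 libraries without DSS replicate 1 or without DSS replicate 2.

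Genes of the absorptive and secretory epithelium and of its metabolism were lower in DSS. Of the mature colonocyte genes 12 of 18 fell and none rose. Slc26a3 (ENSMUSG00000001225.12, chromosome 12, 31390871 to 31473917), the chloride-bicarbonate exchanger of surface colonocytes, had 9603 ± 1626 in water and 942 ± 277 in DSS (log2 fold change -3.37 ± 0.25 SE, limma adjusted p = 0.00375). The water channel gene Aqp8 had 6133 ± 453 and 552 ± 68.3 (-3.48 ± 0.17 SE, adjusted p = 0.00159). Car1, carbonic anhydrase 1, had 6444 ± 697 and 5898 ± 2038 and did not pass (adjusted p = 0.706). Of the goblet cell genes 5 of 15 fell, with Klk1 at 0.0828 of the water level and Bcas1 at 0.240, while Muc2, the main secreted mucin, had 8094 ± 913 and 6033 ± 2298 (adjusted p = 0.315). Of the tight junction genes 10 of 17 fell, among them Cldn3 (0.325 of water, adjusted p = 0.00607), Cldn7 (0.401) and Ocln (0.261, adjusted p = 0.0184), and Tjp1 had 1573 ± 102 and 1510 ± 67.4 (adjusted p = 0.827). The difference of Tjp1 and that of Car1 turned positive with scaling by library size only, at 0.18 and 0.07 (log2). Of the xenobiotic metabolism genes 14 of 22 fell and 1 rose, with the sulphotransferase gene Sult1a1 at 0.0711 of water and the cytochrome P450 gene Cyp2c55 at 0.109. Of the nuclear-encoded respiratory chain genes 14 of 16 fell, among them Cyc1 (0.412) and Cox5a (0.437), and of the fatty acid oxidation and ketogenesis genes 6 of 18, among them the monocarboxylate transporter gene Slc16a1 (0.310). General epithelial genes (Epcam, Krt8, Krt18, Krt19 and 6 more, a list chosen after its values were seen) had medians of -1.14 and -1.82 against water (log2) in the DSS libraries, next to -0.88 and -1.42 for tight junctions and a group median of -1.09 for the respiratory chain. The genes that fell furthest were Mptx1, a pentraxin (8211 ± 758 and 85.4 ± 83.5), Ang4, an antimicrobial ribonuclease of secretory cells (1155 ± 520 and 20.3 ± 23.9), Ugt2b35, Mettl7a2, Sycn and Cps1, the first enzyme of the urea cycle (399 ± 5.01 and 15.1 ± 19.4). No single gene passed in the fit of the 4 libraries without DSS replicate 1 or without DSS replicate 2.

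The 12 lists that fell by camera held the 6 just counted, with adjusted p values from 2.77e-09 (respiratory chain) to 8.33e-06 (fatty acid oxidation) and 0.441 for each with an estimated correlation. Their median log2 fold changes were -1.70 for mature colonocytes, -1.65 for xenobiotic metabolism, -1.62 for goblet cells, -1.20 for tight junctions, -1.09 for the respiratory chain and -0.73 for fatty acid oxidation. Adjusted over the list alone, 13 colonocyte, 9 goblet, 15 respiratory chain and 15 fatty acid genes were lower and none higher, 14 tight junction genes lower and 1 higher, and 15 xenobiotic genes lower and 2 higher. In the fit of 6 libraries 11 colonocyte, 1 goblet, 14 respiratory chain, 0 fatty acid, 11 tight junction and 14 xenobiotic genes were lower and none higher when adjusted the same way. Bile acid and sterol genes (camera adjusted p = 0.000179) and crypt stem cell genes (adjusted p = 0.0076) fell, each at adjusted p = 0.441 with an estimated correlation. In the crypt stem list 5 of 15 genes fell and Cd44 rose, with the stem cell receptor gene Lgr5 at 53.3 ± 14.2 in water and 3.45 ± 0.809 in DSS (limma adjusted p = 0.0134), and 8 were lower and 2 higher adjusted over the list alone. In the bile acid list Fabp6 (0.0836 of water), Nr1h4 and Abcg5 fell and Abca1 rose, and 6 were lower and 2 higher adjusted over the list alone. Interferon response genes fell (adjusted p = 0.00253, 0.607 as the adjusted p with an estimated correlation), with 4 of 20 genes falling and 5 lower adjusted over the list alone. Iigp1 stood at 0.341 and Irf1 at 0.364 of water. Smooth muscle genes fell (adjusted p = 0.0076), with 2 of 13 genes down and 3 adjusted over the list alone. Mitochondrially encoded transcripts fell (adjusted p = 0.0353) with none of 13 passing either way. Both lists stood at an adjusted p = 0.607 with an estimated correlation. Ribosomal protein genes fell by a median log2 of 0.40 (camera adjusted p = 0.000197, adjusted p = 0.494 with an estimated correlation), with 1 of 17 passing, Rps14, and 0 adjusted over the list alone. The interferon list did not pass without DSS replicate 2, mitochondrial transcripts not without water replicate 1 or DSS replicate 2, and smooth muscle not without water replicate 2 or DSS replicate 1. No single gene passed in the fit of the 4 libraries without either DSS library.

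Of the 12 lists that did not pass, 5 held genes called in both directions: the antimicrobial, inflammasome, metal handling, T and NK cell, and immediate-early lists. Of the antimicrobial genes (camera adjusted p = 0.615) 6 of 17 rose and 4 fell, and 7 were higher and 5 lower adjusted over the list alone. Lcn2, the siderophore-binding lipocalin 2, had 4.19 ± 0.501 in water and 1561 ± 550 in DSS (limma adjusted p = 0.00137), and Saa3, a serum amyloid A, was 333-fold higher. The lectin genes Reg3b and Reg3g had no read in water and were at least 11.8-fold and 17.9-fold higher in DSS, against a floor of 3 reads over the group. Retnlb, Ang4, Lypd8 and Pigr fell. Of 13 inflammasome genes 2 rose, Nlrp3 and Mefv, and 3 fell, Nlrp6, Casp1 and Pycard (camera adjusted p = 0.0832). Of 16 metal handling genes 1 rose, Hmox1, and 2 fell, Slc39a5 and Slc30a10 (0.144), and 1 cell cycle gene of 20, Plk1, fell (0.0593). Mefv, Casp1, Pycard and Slc30a10 were chosen after their values were seen. Among cell type lists the camera adjusted p was 0.0918 for enteroendocrine cells, 0.637 for tuft cells, 0.254 for T and NK cells and 0.972 for mast cells and eosinophils. It was 0.329 for adipose tissue, 0.0953 for immediate-early genes, 0.0832 for stratified squamous epithelium and 0.972 for skeletal muscle. The test's direction was up for mast cells where the median was -0.01, and down for skeletal muscle where the median was 0.69. Stratified squamous genes parted the DSS libraries, with a median 0.07 above water (log2) in replicate 1 and 6.59 in replicate 2, and skeletal muscle genes stood at -1.63 and 2.83. Of the 14 genes fixed in advance, Il6 had 1 read in water and a ratio of 275 in DSS (95% counting interval 49.2 to 10859), S100a8 had 2 reads and a ratio of 924 (256 to 7630), and Tnf was 2.82-fold higher without passing (limma adjusted p = 0.103). No single gene passed without either DSS library.

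Counted over all genes, limma called 0 genes in either direction in the fit of the 6 libraries that was set as the test (smallest adjusted p = 0.0576, 4662 of 20307 genes at an unadjusted p under 0.05), as did edgeR and voom. DESeq2 called 1269 higher and 1099 lower. With the DSS and water libraries fitted alone, limma called 1605 genes higher and 1459 lower (smallest adjusted p = 0.00137) and edgeR 1751 higher and 1508 lower, of which 2966 were shared with limma in the same direction. Leaving either DSS plus montmorillonite library out of the fit of 6 gave nearly the same calls as the fit of 4. The library that then remains in that group adds nothing to the spread, so this is no further support. In 62.4% of genes the DSS and water libraries did not overlap, against 33.3% by chance. The calls of the 4 libraries rested on every library: 240 genes were higher and 48 lower without water replicate 1, 253 and 64 without water replicate 2, and 0 passed without DSS replicate 1 (smallest adjusted p = 0.0557) or DSS replicate 2 (0.0761). On simulated data with known changes 11 of the 84 calls of that fit were false, more than the 5% aimed at. That was a single simulated set with 100 genes changed 2-fold and 100 changed 4-fold, far fewer than were called here. It therefore gives no error rate for the real calls. With reads thinned to the shallowest library 12 were higher and 8 lower, and with scaling by library size only 2200 were higher and 893 lower, and that scaling moved the median log2 fold change of all genes from 0.10 to 0.33. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333 and was not used.

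**Figure D2:**
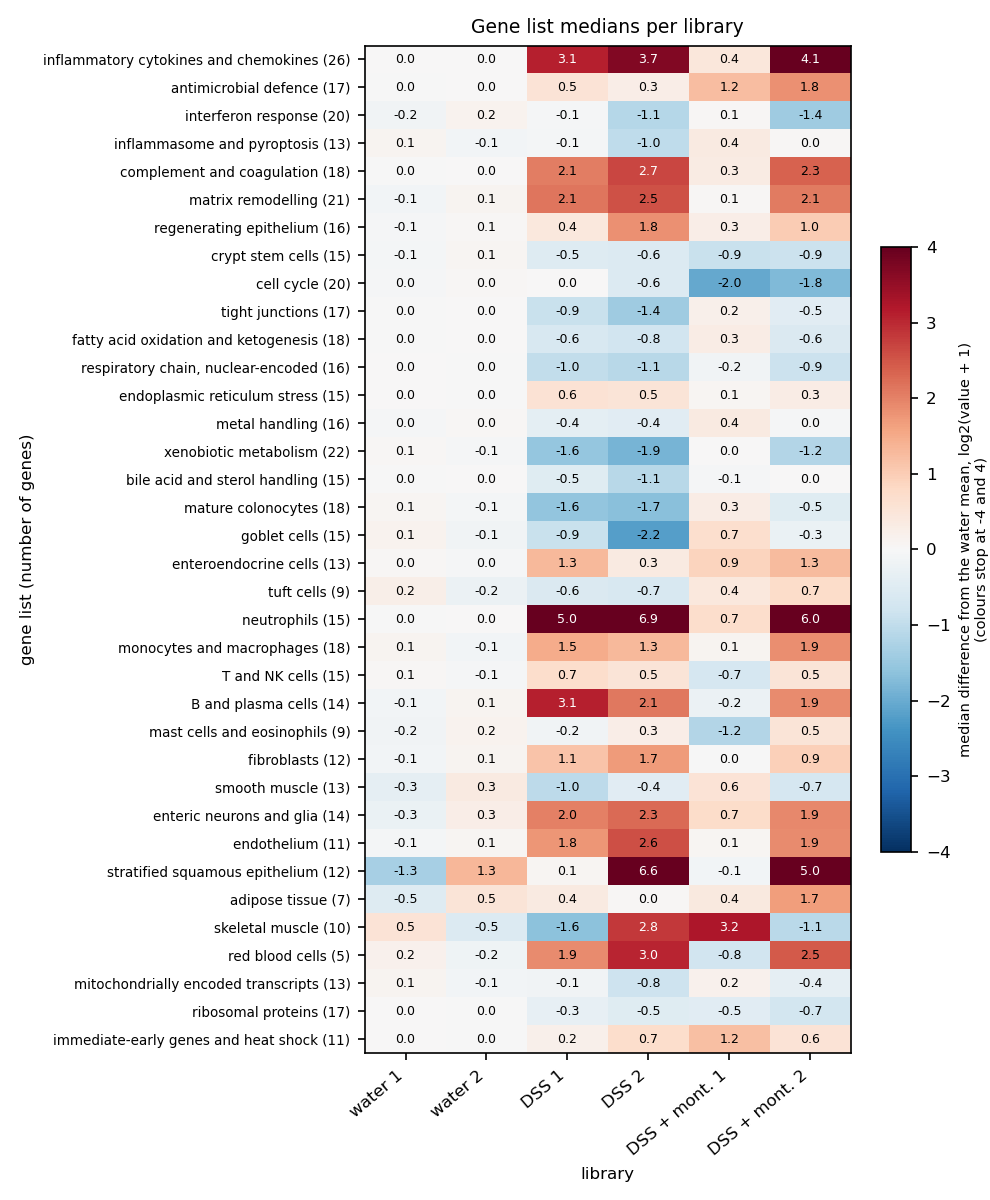
Median difference of each gene list from the mean of the water libraries, in log2(value + 1), with 1 column per library and the number of measured genes in brackets; red is higher and blue lower. Neutrophil genes stand at 4.96 and 6.90 in DSS and at 0.72 and 5.95 in DSS plus montmorillonite, and cell cycle genes at -2.04 and -1.77 in DSS plus montmorillonite.

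The comparison of DSS plus montmorillonite with water asks how far colons given both stood from untreated ones. Genes of cell division were lower in both libraries. All 20 cell cycle genes had a negative log2 fold change, 18 of them without overlap between the groups, and the list fell by a median of 1.82 (camera adjusted p = 1.11e-22, adjusted p = 0.366 with an estimated correlation). Top2a, the topoisomerase of dividing cells, had 1462 and 1556 in water and 234 and 325 in DSS plus montmorillonite, and Cdk1, the mitotic kinase, had 409 and 473 against 89.2 and 107. Crypt stem cell genes fell too (median -0.66, adjusted p = 4.91e-05, adjusted p = 0.366 with an estimated correlation), as did ribosomal protein genes (median -0.63, adjusted p = 1.47e-11, adjusted p = 0.632 with an estimated correlation). Antimicrobial genes rose (median 1.54, adjusted p = 0.000951, adjusted p = 0.632 with an estimated correlation), among them Dmbt1, an epithelial scavenger receptor, at 23546 and 24566 in water and 85519 and 84744 in DSS plus montmorillonite. Adjusted over the list alone in the fit of 6 libraries, 18 cell cycle genes, 3 crypt stem genes and 6 ribosomal protein genes were lower and none higher, and 10 antimicrobial genes were higher and 2 lower. In the fit of the 4 libraries compared, 16, 4 and 0 were lower, and 8 antimicrobial genes higher and 1 lower. Cdk1 and Dmbt1 were chosen after their values were seen.

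Inflammatory genes were higher than in water on average, carried mostly by replicate 2. Lcn2 had 40.3 in replicate 1 and 3392 in replicate 2, S100a8 21.6 and 2502, S100a9 27.3 and 2602, Il1b 90.6 and 901, Il6 1.44 and 205, and Tnf 69.0 and 158. None of them passed over all genes (limma adjusted p from 0.428 to 0.524). Against the few water reads the pooled ratios were 376 for Lcn2 (95% counting interval 172 to 1025), 828 for S100a8 (229 to 6842), 863 for S100a9 (238 to 7132) and 136 for Il6 (23.9 to 5402), and at least 38.5 for Reg3b (1 read in replicate 1 and 96 in replicate 2) and 17.4 for Reg3g (6 and 38). Lists that rose were neutrophils (median 3.24, 3.20 with members without a read at their bound, camera adjusted p = 3.6e-06), cytokines (1.96, 2.10 at the bound, 0.00513), enteric neurons and glia (1.54, 3.4e-06), and complement (1.33, 4.91e-05). So did enteroendocrine cells (1.25, 0.00141), regenerating epithelium (1.10, 0.000422), matrix remodelling (0.99, 0.97 at the bound, 4.91e-05), endothelium (0.96, 0.00147), monocytes and macrophages (0.82, 4.91e-05) and immediate-early genes (0.72, 0.00126). Lists that fell were interferon response (-0.68, 0.000111), xenobiotic metabolism (-0.67, 0.0146) and the respiratory chain (-0.52, 2.22e-05), where general epithelial genes stood at 0.12 and -0.82 in the replicates. With an estimated correlation none of these passed: the adjusted p was 0.697 for cytokines, 0.651 for endothelium and 0.632 for the others. Adjusted over the list alone in the fit of 6 libraries, 7 neutrophil genes, 4 neuronal genes and 3 immediate-early genes were higher and 1 cytokine gene and 1 interferon gene lower, with 0 in the other lists that passed. In the fit of the 4 libraries 0 neutrophil, 0 neuronal, 2 immediate-early and 1 enteroendocrine genes were higher, and 1 cytokine and 1 interferon gene lower. Without DSS plus montmorillonite replicate 2 the cytokine, interferon, complement, matrix, respiratory chain, xenobiotic, macrophage and endothelial lists did not pass, and without replicate 1 the immediate-early list did not. Stratified squamous genes stood -0.11 from water (log2) in replicate 1 and 5.01 in replicate 2, and skeletal muscle genes 3.24 and -1.09. The other 19 lists did not pass, with mature colonocytes at a median of -0.24 (adjusted p = 0.35) and goblet cells at 0.20 (adjusted p = 0.203).

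Over all genes limma called 0 in either direction (smallest adjusted p = 0.268, 2058 genes at an unadjusted p under 0.05), as did edgeR, voom and limma on the 4 libraries alone, while DESeq2 called 149 higher and 194 lower. Without DSS plus montmorillonite replicate 1, and with replicate 2 assumed to vary like the other groups, limma called 649 higher and 329 lower and 26 lists passed in place of 17. The groups did not overlap in 40.8% of genes, against 33.3% by chance.

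The comparison of DSS plus montmorillonite with DSS asks what the clay added to DSS changed. Goblet cell and colonocyte genes were higher, and cell cycle genes lower, than in DSS alone. All 15 goblet cell genes had a positive log2 fold change and the list rose by a median of 1.74 (camera adjusted p = 3.14e-11, adjusted p = 0.541 with an estimated correlation). Muc2 (ENSMUSG00000025515.15, chromosome 7, 141690340 to 141754693) had 7658 and 4408 in the DSS libraries and 20424 and 17255 with montmorillonite, against 8739 and 7448 in water, with a log2 fold change of 1.69 ± 0.32 (SE, n = 2) over DSS that missed the threshold over all genes (limma adjusted p = 0.279). Mature colonocyte genes rose by a median of 1.58 (camera adjusted p = 1.24e-10, adjusted p = 0.408 with an estimated correlation). Slc26a3 had 746 and 1138 in DSS and 14220 and 3461 with montmorillonite (2.93 ± 0.62 SE, limma adjusted p = 0.279), and Aqp8 600 and 503 against 6652 and 805. Cell cycle genes fell by a median of 1.62 (camera adjusted p = 2.43e-16, adjusted p = 0.408 with an estimated correlation), with 19 of 20 members below both DSS libraries in both libraries, Plk1 being the exception. Top2a had 1580 and 903 in DSS and 234 and 325 with montmorillonite (log2 fold change -2.11, limma adjusted p = 0.266). General epithelial genes, the list chosen after its values were seen, were higher as well, with medians against water of -1.14 and -1.82 in DSS and of 0.12 and -0.82 with montmorillonite (log2). Adjusted over the list alone in the fit of 6 libraries, 10 goblet and 11 colonocyte genes were higher and 19 cell cycle genes lower, and in the fit of the 4 libraries compared 0, 5 and 16.

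**Figure D3:**
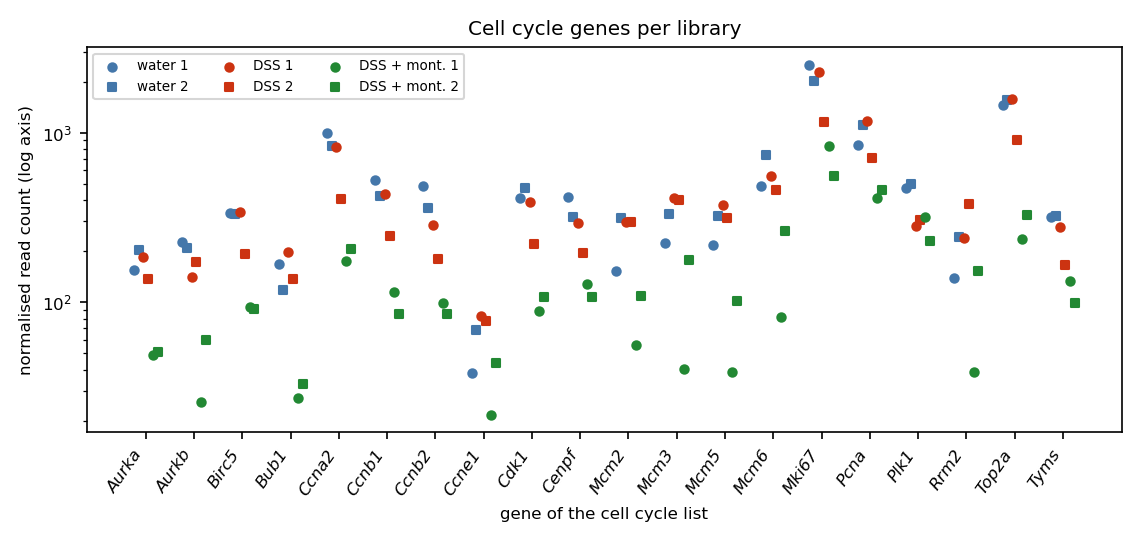
Normalised read counts (log axis) of the 20 measured cell cycle genes, with 1 point per library. Both DSS plus montmorillonite libraries lie below all 4 others in 17 of the 20 genes; Top2a, for example, is at 234 and 325 there and at 903 or more in the others.

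Epithelial metabolism and barrier lists were higher than in DSS as well. Tight junctions (median 0.91, camera adjusted p = 3.67e-07), fatty acid oxidation (0.65, 3.85e-07) and bile acid handling (0.46, 0.000101) rose, each at an adjusted p = 0.541 with an estimated correlation, and xenobiotic metabolism (1.34, 9.77e-06) and metal handling (0.74, 0.00235) rose at 0.408 as that adjusted p. The respiratory chain (0.53, 9.65e-06), inflammasome (0.85, 0.00272) and antimicrobial lists (0.73, 0.00349) rose at an adjusted p = 0.558 with an estimated correlation, and smooth muscle (0.49, 0.0199) at 0.685. The general epithelial list stood at 0.12 and -0.82 against water, compared with -1.14 and -1.82 in DSS. Stromal and immune lists fell on the group average: B and plasma cells (-1.75, 3.54e-06), red blood cells (-1.64, 0.0199), cytokines (-1.55, 0.000767), endothelium (-1.20, 0.00352), matrix remodelling (-1.16, 5.95e-06), and fibroblasts (-1.01, 0.00173). Smaller median differences were those of complement (-0.89, 0.0358), mast cells and eosinophils (-0.79, 0.0324), enteric neurons (-0.65, 0.0164), endoplasmic reticulum stress (-0.28, 0.03) and ribosomal proteins (-0.27, 0.00502), which fell too. For these 11 lists the adjusted p was 0.558 to 0.685 with an estimated correlation. Cytokine medians against water (log2) were 3.11 and 3.71 in DSS, and 0.45 and 4.08 in DSS plus montmorillonite replicates 1 and 2. In replicate 2 the red blood cell (2.45), endothelial (1.89) and complement (2.35) medians lay between those of the DSS libraries. Its mast cell median (0.52) lay above both. Its medians of the remaining lists lay below both. Adjusted over the list alone in the fit of 6 libraries, 6 tight junction, 5 antimicrobial, 3 bile acid, 2 fatty acid, 1 metal handling and 1 inflammasome gene were higher, and 0 genes passed in the other lists called here. Fitted on the 4 libraries, 3 bile acid genes were higher and 0 genes passed in the others. As values without a call, the members with the smallest p included Retnlb, a goblet cell product (log2 fold change 2.07), Abcg8 (1.92), Sprr2a1 (1.72), Cyp2d34 (1.68), Cldn3 (1.52), Slc39a4, a zinc importer (1.35), Gsdmd, the pore former of pyroptosis (1.11), Cox5a (0.82) and Irf1 (0.76). Those with negative values were Tnc (-2.05), Ccl7 (-1.70), Thbd (-1.55), Myc (-1.55) and Creld2 (-0.82). The neutrophil list did not pass (median -2.38, adjusted p = 0.338), and neither did the other 12 lists.

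The replicates weighed on these list calls unequally. Without DSS plus montmorillonite replicate 1, 13 of the 23 lists passed in the same direction, the cytokine, complement, matrix, respiratory chain, endoplasmic reticulum stress, mast cell, smooth muscle, neuronal, endothelial and red blood cell lists being lost. Without its replicate 2, 21 passed, the antimicrobial and ribosomal lists being lost. Without DSS replicate 1, 19 passed (lost: endoplasmic reticulum stress, mast cells, smooth muscle, ribosomal proteins), and without DSS replicate 2, 16 (lost: inflammasome, complement, mast cells, fibroblasts, neurons, endothelium, red blood cells). The cell cycle, goblet cell, colonocyte, tight junction, fatty acid, xenobiotic, bile acid, metal handling, and B and plasma cell lists passed in each of these. Scaling by library size only moved the median log2 fold change of all genes from -0.07 to -0.31, and the complement, mast cell and red blood cell lists then did not pass. Over all genes limma called 0 in either direction (smallest adjusted p = 0.266, 2291 genes at an unadjusted p under 0.05), as did edgeR, voom and limma on the 4 libraries alone, while DESeq2 called 473 higher and 167 lower. Without DSS plus montmorillonite replicate 2 limma called 1059 higher and 996 lower. The groups did not overlap in 39.9% of genes, against 33.3% by chance.

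**Figure D4:**
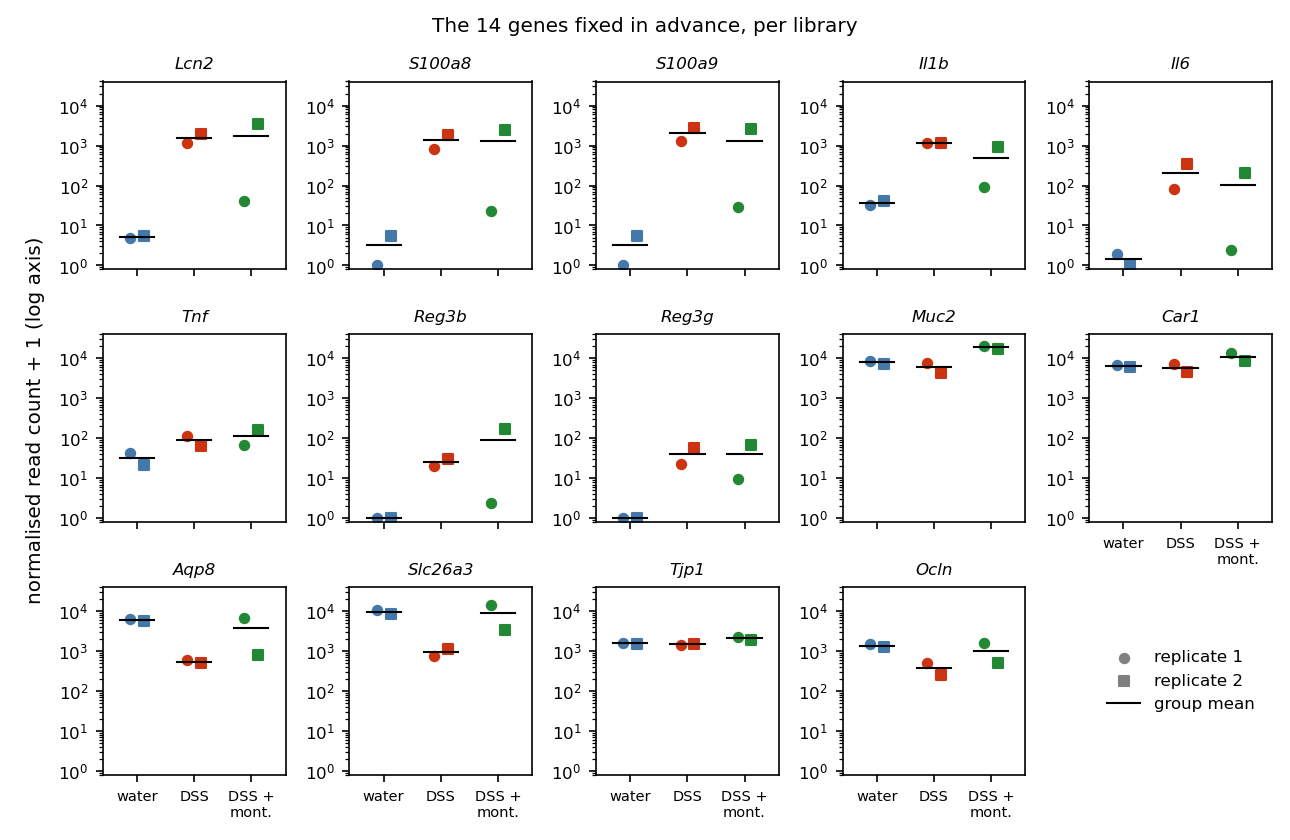
Normalised read count + 1 (log axis) of the 14 genes fixed in advance, with 1 point per library (circles replicate 1, squares replicate 2) and a line at the group mean. Lcn2 stands at 40.3 and 3392 in the DSS plus montmorillonite libraries, against 1172 and 1950 in DSS, and Muc2 at 20424 and 17255, against 7658 and 4408.

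How much of the DSS change was present with montmorillonite was measured over the 3064 genes called in the fit of the DSS and water libraries, as the log2 fold change of DSS plus montmorillonite over water divided by that of DSS over water. The median share was 0.453 for the group, 0.0390 for replicate 1 and 0.850 for replicate 2. In 20 simulations in which montmorillonite had no effect the group median was 0.937 (range 0.931 to 0.943). Each simulation took the genes called in its own DSS and water libraries, 3825 to 4282 and not the same 3064. Its replicates varied around 1 mean by the dispersion of the DSS and water libraries, each gene independently. The real DSS plus montmorillonite libraries were further apart, with a median standard deviation of 0.35 against 0.15 in water and 0.24 in DSS. Their genes also moved together, so the simulated range is too narrow to say whether montmorillonite had an effect. Genes higher in DSS had a median share of 0.530 (0.108 and 0.938 in the replicates) and genes lower in DSS 0.324 (-0.0397 and 0.699). Leaving out replicate 1 gave 0.850 and leaving out replicate 2 gave 0.0390. These genes were picked on the same DSS and water libraries that give the divisor. With 3064 genes picked on replicates 1 of DSS and water and measured on their replicates 2, the group share was 0.445 (0.0502 and 0.828 in the DSS plus montmorillonite replicates). With the roles exchanged it was 0.597 (0.0951 and 1.07). The log2 fold changes of the 2 comparisons with water had a Pearson r of 0.738 across 20307 genes. Simulations with equal expected values in the 3 groups, and 1 dispersion per gene for all groups, gave 0.539 (0.528 to 0.549). The real water libraries varied less than the others (median standard deviation 0.15 against 0.24 and 0.35). The simulated values therefore need not be those that sharing these water libraries alone would give. Without DSS plus montmorillonite replicate 2 the real r was 0.293, a setting that was not simulated. The covariance was 0.862 against 0.292 in those simulations, and 75.2% of genes had the same sign against 67.6%. DESeq2 called 116 genes higher and 38 lower in both comparisons. Comparisons without a library in common would share 12.7 and 14.4 by chance, and sharing the water libraries raises these numbers by an amount that was not simulated.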

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

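Chosen after the data were seen were the use of edgeR on the recovered reads, the TMM factors, the thinned reads, every setting that joins a change of scaling, depth or replicates to the fit of 4 libraries, and the choice of genes behind the median share of the DSS change. The edgeR test on 6 libraries had been set in advance for a file of counts, and limma for normalised values. For DSS against water, where limma on 6 libraries called 0 genes, the genes higher and lower were 1269 and 1099 with DESeq2, 1605 and 1459 with only the 4 libraries compared, 1751 and 1508 with edgeR on those 4, 1656 and 1263 with TMM factors on them, 2200 and 893 with library size only on them, and 12 and 8 with thinned reads on them, where fewer reads were tested by construction. With the replicate number as a replicate block they were 326 and 352, of which 627 were shared with the 3064 of the 4 libraries; the replicates share only a number, the block called 0 in the other 2 comparisons, and the deviations of replicate 1 from the group means correlated at 0.229 (water and DSS), 0.152 (water and DSS plus montmorillonite) and 0.407 (the DSS-treated groups). Leaving out 1 library gave 0 to 1615 higher and 0 to 1493 lower in the fit of 6. In the fit of 4 it gave 240 and 48 without water replicate 1, 253 and 64 without water replicate 2, and 0 without either DSS replicate. The increase in calls without the DSS plus montmorillonite libraries goes with their wider spread within the group; for the other settings the cause was not tested.

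For DSS plus montmorillonite against water DESeq2 called 149 higher and 194 lower, and leaving out 1 library gave 0 to 649 higher and 0 to 329 lower. Against DSS it called 473 higher and 167 lower, and leaving out 1 library gave 0 to 1059 and 0 to 996. A group left with 1 library was assumed to vary like the others. The 24, 17 and 23 lists changed by camera fell to 0, 0 and 0 with an estimated inter-gene correlation and to 0, 0 and 0 with fry. Leaving out 1 library of the fit of 6 gave 23 to 28, 15 to 26 and 17 to 27 lists. The median share of the DSS change ranged from 0.0390 to 0.850 and the correlation of fold changes from 0.293 to 0.806 when 1 library was left out, the lowest r being that without DSS plus montmorillonite replicate 2. Of 2870 values of named genes under an alternative, 665 passed where limma on 6 libraries had not, most of them DSS against water genes that were named because they pass in the fit of 4, 0 passed with the opposite sign, and 26 differed in sign with neither passing. With the replicate block 22 of the 23 lists of DSS plus montmorillonite against DSS passed in the same direction, the endoplasmic reticulum stress list being lost. Median-of-ratios factors were not run as an alternative, since the deposited factors are the same.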

Other observations

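The genes and the MHC class II and epithelium lists of this part were chosen after their values were seen, as were the tests on swapped and wrong labels, on the share of epithelium and on the degree of inflammation; the tests on sequencing depth were not. MHC class II genes were lower than in water in all 4 DSS-treated libraries, with a median log2 difference of -1.86 and -1.90 in DSS and of -1.36 and -1.66 in DSS plus montmorillonite. The medians of the epithelium list were -1.14 and -1.82 in DSS and 0.12 and -0.82 in DSS plus montmorillonite. H2-Ab1, an antigen-presenting chain, had 8713 and 7521 in water, 2051 and 1839 in DSS and 2851 and 2106 in DSS plus montmorillonite (DSS against water, limma fit of 4 libraries, adjusted p = 0.00496). Of the 7 genes 6 passed in that fit, Ciita, the class II transactivator, being the exception (adjusted p = 0.192), and no gene passed without DSS replicate 1 or without DSS replicate 2. Other genes below water in all 4 were the urea cycle genes Cps1 (395 and 403 in water, 28.8 and 1.44 in DSS, 37.4 and 7.27 in DSS plus montmorillonite) and Otc, and the stem cell genes Lgr5 (63.3 and 43.2, 4.02 and 2.88, 0 and 1.82) and Ascl2 (49.0 and 59.1, 12.7 and 2.88, 1.44 and 0). Smoc2, another stem cell gene, had 200 and 227 in water, 315 and 608 in DSS, and 84.9 and 343 in DSS plus montmorillonite.

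Both DSS plus montmorillonite libraries lay beyond all 4 others by more than 1.5-fold in 232 of 13914 genes, 37 higher and 195 lower. The pair of water libraries did so in 475 genes and the pair of DSS libraries in 536, but so did pairs across groups, replicate 2 with DSS replicate 2 in 840 and replicate 1 with water replicate 1 in 232, so the number alone does not mark the group. Among the higher ones were Dmbt1, the mucin gene Muc2, the mucin-type glycosyltransferase genes B3galt5 (8326 and 8243, against 4090 or less) and Gcnt3 (489 and 500, against 292 or less), and Ccl20, a chemokine of the epithelium (84.9 and 99.9, against 49.2 or less). Among the lower ones were genes of mitosis outside the list fixed in advance, such as Cdc20 (70.5 and 74.5, against 278 or more) and Foxm1 (28.8 and 49.1, against 151 or more).

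The DSS plus montmorillonite libraries lay far apart, replicate 1 near water and replicate 2 near DSS. No water library had DSS-like neutrophil values: the lowest DSS mean of the neutrophil list lay 4.33 above the highest water mean (log2), where the water libraries differed by 0.407. A swap with a water library would show there only if DSS plus montmorillonite left neutrophil genes as high as DSS does. Whether it does is not known, so these values cannot exclude a swap. A water library with a wrong label would share few genes beyond all others with replicate 2, as the water libraries did (11 and 14). Replicate 1 shared 232 with it (and 232 and 163 with the water libraries, which goes with its nearness to water). The MHC class II median of replicate 1 was -1.36, against -1.86 and -1.90 in DSS, and the water libraries were within 0.04 of their mean. That list was chosen after it was seen to be low in all 4 DSS-treated libraries, so it cannot test the label. Sequencing depth left the gap as it was, with a difference between the replicates in the share of the DSS change of 0.813 at equal depth and 0.811 at full depth. Genes of other tissues also parted the replicates, with stratified squamous medians of -0.11 and 5.01 and skeletal muscle medians of 3.24 and -1.09. Squamous genes were higher in replicate 2 of DSS (0.07 and 6.59) and of water (-1.33 and 1.33) too, whereas skeletal muscle genes had the reverse order in DSS (-1.63 and 2.83). These values go with a difference in the tissue sampled, which was not tested. A difference in how the mice responded to DSS or to montmorillonite may underlie the gap, which was not tested, and an unrecorded difference in dose, sampling or library preparation stays open.

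Cell cycle genes were low in both DSS plus montmorillonite libraries. At equal depth their median against water was -1.73, against -1.82 at full depth, so fewer reads do not account for it. A smaller share of epithelium would lower epithelial genes as far, but the epithelium median lay above the upper quartile of the cell cycle list in both libraries, by 0.254 (log2) in the closer of them. In replicate 2 the lowest epithelial gene, at -1.30, lay under that quartile (-1.08). The list holds general epithelial genes, so it cannot tell whether the share of dividing crypt cells within the epithelium changed. Crypt stem cell genes stood at -0.89 and -0.86 in these libraries. The degree of inflammation, read from neutrophil genes, does not order the libraries in this way: the medians of 0.72 and 5.95 lie on either side of DSS replicate 1 (4.96), yet the lowest DSS median of the cell cycle list lay 1.20 (log2) above the highest of theirs, where the DSS libraries differed by 0.59. An effect of montmorillonite, a change of cell shares within the epithelium and a preparation shared by these libraries stay open, none of them tested.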
